A study of marine metagenome with 17 samples.

How the data were processed

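Surface seawater microbes of Monterey Bay that passed a 1 µm filter were incubated in 12 L bottles at 20 °C for 12 or 36 h with a 13C-labelled carbon source at 1 µM carbon, per the labels' protocols. The carbon sources were acetate, amino acids, glucose, lipids, protein and starch. Total RNA was hybridised to an oligonucleotide array with probes for named microbial taxa, and the spots were imaged by secondary ion mass spectrometry (NanoSIMS). In this assay, called Chip-SIP, a spot whose RNA came from organisms that built the label into RNA carries more 13C. The series has 17 samples. Of these, 15 are isotope arrays with a file each, and 2 are fluorescence arrays, which were not analysed here.

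The deposited 12C14N and 13C14N columns hold the secondary ion signal of each spot, per the file headers, with no normalization. The deposited 13C column holds enrichment in per mil, per the file headers, which is a ratio of isotopes: the 13C14N to 12C14N ratio of the spot over the ratio of the summed control spots of the same panel, minus 1, times 1000. Each array carries 3 panels of probes, named MB, PAC and SPOT in the files. Recalculation from the ion signal gave the deposited per mil values of 40 of the 45 panels within 0.01 per mil. The other 5 panels are headed as averages over imaging runs in the files, and their deposited values were used as they stand. The software that drew the spots and any filter on spots are not given in the sources used here.

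Probe sets were taken by the names in the files. They are used here as the files give them, since the files do not spell them out. On the SPOT panel, 33 names start with 890 and 66 with SPOTS. A probe set held about 10 spots on the MB panel and 12 on the PAC panel, each spot with another probe of the taxon. On glucose 12 h replicate 2, 85 spots carried names that belong to another panel and were left out. The deposited name differed from the name at that grid position on the other arrays for 32 spots of glucose 12 h replicate 1, 89 of glucose 12 h replicate 2 and 32 of the glucose 36 h array. Spots with no probe name numbered 51 on acetate 12 h replicate 1 and 71 on each other array, and they entered no comparison. Spots with a value that is not a number (9 in all) were also left out. The value of a probe set on an array was the mean over its spots of the deposited per mil value. Probe sets with at least 3 spots on every array were compared between arrays: 282 of 390, of which 181 were on the MB panel, 101 on the PAC panel and 0 on the SPOT panel.

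Arrays were grouped by substrate and time from the labels, which gave 6 groups of 2 arrays at 12 h and 3 groups of 1 array at 36 h (acetate, amino acids and glucose). The labels do not say that the arrays of a group came from separate bottles, so p-values measure only the spread between these arrays, which may be technical. Replicate numbers only name the arrays. No pair of arrays had the same 12C14N signal at any grid position that both held, in 105 pairs. Image names and column headings in the files fall into 3 imaging sets. Numbers A1 to A6 hold both lipid arrays, both protein arrays, acetate 12 h replicate 2 and amino acids 12 h replicate 2. Numbers A7 to A12 hold the 3 arrays at 36 h, acetate 12 h replicate 1, amino acids 12 h replicate 1 and glucose 12 h replicate 1. The prefix 838 marks both starch arrays and glucose 12 h replicate 2, called the starch set here. Where a set held more than 1 group, the values within the set and the values with the set as a block are given beside the comparison.

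Differences between groups were tested on the per mil scale with limma 3.58.1 in R 4.3.3, in 1 fit over the 15 arrays and 9 groups with 6 residual degrees of freedom. Each substrate was set against the mean of the other 5 at 12 h, protein against amino acids, starch against glucose, lipids against acetate, and 36 h against 12 h. The single array at 36 h was assumed to vary like the groups of 2. With the imaging set as a block, the fit left 4 residual degrees of freedom. Without centring, limma then gave every probe set the same SD of 12.9 per mil. Its p-values therefore ignore differences in spread between probe sets and can be far too small for those that vary more. Adjusted p-values follow Benjamini and Hochberg within a comparison, with a threshold of 0.05. Enrichment on an array was tested for each probe set against the control spots of the array with a one-sided permutation test over spots (100000 permutations), which compares spots and not incubations, and counted for a group where every array of the group passed. Array medians and correlations between arrays were tested by one-sided permutation of the array labels (100000). The 23 taxonomic groups were matched by name, including names that are the start of a group's term (such as flavo or roseo). The name stems bacter, bacteria, nitroso, marino and rhodo were taken as ambiguous and put in no group. The terms were fixed beforehand, but the match to starts of terms and this exclusion were not among them. Of the 23 groups, 15 had at least 3 members, and 185 probe sets fell in a group and 97 in none. Groups were tested with camera of limma, with a preset correlation of 0.01 and with an estimated correlation, and a camera result compares a group with all other probe sets. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

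Tests, the terms of the taxonomic groups and the rule for named probe sets were fixed before the data were examined. By that rule, up to 5 probe sets with the largest difference in each direction are named in a comparison, among those past the threshold whose arrays all lie on one side. Where none passed, the 2 with the largest difference are named. The rule also takes up to 5 probe sets per group for enrichment over control spots, and the member of each taxonomic group with the highest mean over the 15 arrays. The alternatives listed at the same time were values standardised within an array, quantile normalization, the median over spots, a minimum of 10 spots, the log2 ratio scale, only the arrays compared, array weights, other backgrounds and leaving out each array in turn. Further alternatives were chosen after seeing the data: the imaging set as a block, with and without centring of arrays, centring of arrays, of panels and of grid lines, names by grid position, permutation of labels within imaging sets, families by name stem, and 2 treatments of a step in a panel. That step lay on the MB panel of amino acids 12 h replicate 2, where the median of the probe spots was -3.87 per mil on grid lines up to 28 and 35.3 per mil from line 29 to line 43. One treatment set each part of the panel against the control spots of that part, and the other left out the 64 probe sets with a spot in the second part.

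The scripts were tested on simulated data. For limma, independent normal noise was drawn with the mean and fitted SD of each probe set on the real arrays. It had no array-wide shift, panel step or correlation between probe sets. For the test over control spots, normal values of a fixed SD were drawn without the arrays. The shares called below need not hold for the real arrays, whose probe sets shift together. For amino acids against the other substrates, the limma step called 15% of 20 changed probe sets raised by 20 per mil, 80% of those raised by 40 and 100% of those raised by 80, and 0.450% of unchanged ones. For 36 h against 12 h it called 0%, 30% and 90% at the same sizes. The test over control spots called 52.5% at 20 per mil and 100% at 40 per mil.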

Results

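The use of 6 carbon sources by surface seawater microbes was measured as the 13C content of RNA bound to taxon probes. At 12 h, 2 arrays each were measured for acetate, amino acids, glucose, lipids, protein and starch, and at 36 h 1 array each for acetate, amino acids and glucose. An array held 3342 to 4318 probe spots, and the total 13C14N signal of an array ranged from 3074645 to 11237245. Counting error of the ions gave a median standard error of 7.44 to 13.7 per mil for a probe set on an array. The number of arrays limits the precision of all comparisons between groups. Values are 13C enrichment in per mil over control spots, with the SD over arrays.

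The question was first how much 13C the hybridised RNA carried after each incubation. The median over 282 probe sets was highest with amino acids (20.7 ± 25.2 per mil, n = 2) and glucose (11.3 ± 12.2 per mil, n = 2) at 12 h. It was 5.79 ± 3.80 per mil with starch, 2.22 ± 0.138 with protein, 1.93 ± 2.02 with acetate and -4.12 ± 4.05 with lipids (n = 2 each). At 36 h, the median was 20.4 per mil with glucose, 19.1 with amino acids and -2.37 with acetate, on 1 array each. Replicate arrays differed widely: amino acids gave 38.5 and 2.81 per mil and glucose 20.0 and 2.66 per mil. The ratio of the control spots differed between arrays too. Against the mean control ratio of all panels and arrays, the medians were 186 and -14.2 per mil with amino acids, 63.2 and -8.49 with glucose and -110 and 6.89 with starch. Medians taken that way did not differ between substrates (permutation test, F = 0.894, p = 0.589). Nor did the medians over control spots differ between the 6 substrates beyond the spread between arrays (permutation test, F = 1.10, p = 0.257, n = 2 per substrate). Without amino acids replicate 2, the permutation p was 0.0130. In the imaging set A7 to A12, unnamed spots averaged 114 per mil on amino acids replicate 1, 107 on glucose 36 h, 79.995 on amino acids 36 h, 56.2 on glucose replicate 1, 29.2 on acetate replicate 1 and 1.77 on acetate 36 h. Outside that set, unnamed spots averaged -20.2 to -3.60 per mil.

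**Figure D1:**
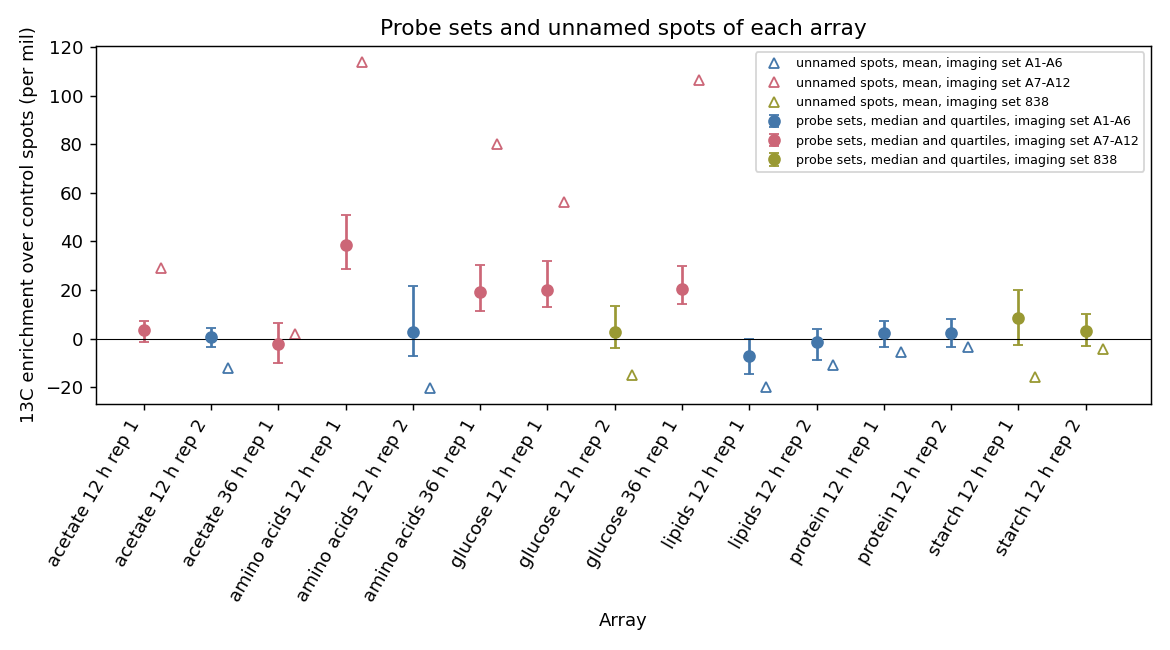
13C enrichment in per mil on each of the 15 arrays (y axis), with the median and quartiles over probe sets as filled circles and the mean of the unnamed spots as open triangles, coloured by imaging set. Amino acids replicate 1 had the highest median at 38.5 per mil, and its unnamed spots averaged 114 per mil.

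Profiles over probe sets resembled each other little between arrays. The mean Spearman correlation across the 282 probe sets, which are not independent replicates, was 0.314 for the 6 pairs of arrays of one substrate and 0.269 for the 60 pairs of different substrates at 12 h. This difference of 0.0450 was not past the threshold (permutation test, p = 0.144). It was past the threshold without acetate replicate 2 (permutation p = 0.0406) and after the mean of each probe set over the arrays was subtracted (permutation p = 0.0045). With labels permuted only among arrays of one imaging set, the permutation p was 0.261, and 0.00911 after the means were subtracted. Within an imaging set, pairs of one substrate averaged 0.363 (3 pairs) and pairs of different substrates 0.297 (18 pairs). Between sets, the means were 0.265 (3 pairs) and 0.257 (42 pairs). After the means were subtracted, the averages were 0.198 and 0.0841 within a set and 0.0806 and -0.143 between sets, so that pairs of different substrates in one set averaged as high as pairs of one substrate in different sets.

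Which taxa carried label above the control spots was asked for each substrate. With amino acids at 12 h, alpha1 of the Alphaproteobacteria stood at 130 ± 30.4 per mil, alpha8 at 100.5 ± 49.0, epsilon, the only probe set of the Epsilonproteobacteria, at 99.7 ± 8.17, lotka_1 at 92.5 ± 47.2 and Arct96B at 64.9 ± 22.3 (n = 2 each). With glucose, rhodobacter of the Rhodobacterales, an order with many heterotrophs of coastal waters, stood at 120.3 ± 59.8 per mil, lotka_1 at 104 ± 19.1, alpha8 at 98.5 ± 103, epsilon at 85.4 ± 31.4 and roseo_12, also of the Rhodobacterales, at 65.1 ± 42.2 (n = 2 each). With starch, 890_2_E_2 stood at 98.5 ± 11.1 per mil, NS9_2 of the Bacteroidetes at 87.4 ± 3.82, glacie1 of the Alteromonadales at 86.2 ± 2.88, flavo_2 of the Bacteroidetes at 76.7 ± 28.0 and acido1 at 70.1 ± 8.56 (n = 2 each). No probe set passed on both arrays with protein, acetate or lipids, where single arrays gave 7 and 2 probe sets with protein and 0 with acetate and lipids. At 36 h, alpha1 had 181 per mil with amino acids and 172 with glucose, 890_2_E_2 had 172 and 259, rhodobacter 138 with amino acids, planctomycetes 121 with amino acids and fluvii_1 of the Bacteroidetes 225 with glucose. SPOTSAUG01_5m75 had 113 per mil with amino acids and 143 with glucose at 36 h, and alpha8 had 137 with glucose. With acetate at 36 h the 5 probe sets above the control spots were SPOTSAUG01_5m781 at 33.5 per mil, SPOTSMAY03_890m4 at 25.7, SPOTSAPR01_5m19 at 23.9, SPOTSAUG01_5m84 at 22.02 and 890_4_D_5 at 19.8.

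By the permutation test over spots, 70 probe sets exceeded the control spots on both amino acid arrays, out of 366 on replicate 1 and 73 on replicate 2. Independent lists of these lengths would share 68.5. With each part of the stepped panel set against its own control spots, 53 passed on both. For glucose the counts were 37 on both arrays, 312 and 45 on single arrays and 36.0 for independent lists, and for starch 25, 81 and 33, and 6.85. At 36 h, 302 probe sets passed with glucose, 209 with amino acids and 5 with acetate. Control spots were also replaced by random draws from all probe spots of the array, with panels pooled and the probe set's own spots included. Against these, 4 passed with amino acids, 0 with glucose, 7 with starch, 2 with protein, 2 with acetate and 1 with lipids at 12 h.

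Across the 6 substrates at 12 h, 11 probe sets differed by the F-test of limma, and 54 had an unadjusted p under 0.05. Epsilon had the lowest adjusted p (0.00278) and was highest with amino acids and lowest with lipids at 2.49 ± 2.18 per mil (n = 2). The next were alpha1 (adjusted p = 0.00501), lotka_1 (0.00676), and NS9_2, OM60_2 and flavo_2 (0.00837 each). OM60_2, of a gammaproteobacterial clade of coastal waters, stood at 63.6 ± 15.8 per mil with starch, 55.8 ± 13.98 with amino acids and 54.6 ± 1.94 with glucose, against 2.87 ± 1.205 with lipids and 3.31 ± 2.14 with acetate (n = 2 each). The other probe sets past the threshold were acido1, Arct96B, mrgrpA7, eurygrpII5 and acido4. Without amino acids replicate 2 the count was 135, without either lipid array 2, without glucose replicate 2 it was 22, without amino acids replicate 1 it was 17, without an acetate array 6 or 5, without a protein array 6 and without a starch array 4. With the imaging set as a block it was 28.

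Amino acids are the monomers of protein. With them, alpha1 was 102 ± 13.2 per mil (difference ± SE) above the mean of the other 5 substrates (limma, adjusted p = 0.000361), with 130 ± 30.4 per mil against 27.9 (n = 2). Epsilon was 69.8 ± 11.1 per mil above (adjusted p = 0.00201), lotka_1 58.5 ± 14.003 (0.0168), Arct96B 50.7 ± 10.1 (0.0104) and alpha8 73.6 ± 24.6 (0.0482). With grid lines centred, alpha1 was 64.5 per mil above (limma, adjusted p = 0.0412) and lotka_1 40.8 (0.0412). Epsilon (28.8 per mil, 0.0961), Arct96B (15.4, 0.478) and alpha8 (39.3, 0.550) did not pass there. Alpha1 exceeded the other substrates by 86.7 per mil within A1 to A6 and by 112 within A7 to A12, and the values were 96.7 and 36.4 for epsilon, 39.9 and 55.3 for lotka_1, 46.4 and 63.0 for Arct96B and 61.0 and 35.7 for alpha8. The A1 to A6 values rest on amino acids replicate 2, whose MB panel holds the step. With the imaging set as a block, alpha1 was 96.8 per mil above (adjusted p = 1.5e-14), epsilon 56.5 (0.00011), Arct96B 50.9 (0.000465), lotka_1 50.5 (0.000472) and alpha8 29.9 (0.0562). These p-values rest on the SD that the block fit shares over all probe sets.

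In all, 54 of the 282 probe sets were higher with amino acids and 0 lower, and the block fit gave 37 and 2. Of the 54, 50 were among the 64 probe sets with a spot in the raised second part of the MB panel of replicate 2, and outside it flavo_7, lotka_1, oceano_4 and syntropho_1 passed. With each part of that panel set against its own control spots, 4 passed: alpha1 at 92.9 per mil (adjusted p = 0.000959), epsilon at 60.4 (0.00409), lotka_1 (0.0359) and eurygrpII5, while Arct96B (41.8 per mil, 0.0637) and alpha8 (64.5 per mil, 0.0749) did not. The median difference of the 54 fell from 37.0 to 29.6 per mil there (median SE 9.82 and 10.2), while that over all probe sets went from 17.3 to 19.9. Of the 54, 51 kept an unadjusted p under 0.05, though they were chosen on the same arrays. With the second part left out, 1 passed. No probe set passed with standardised or quantile normalized values, where limma gave 0. The highest adjusted p on leaving out an array was 0.250 for lotka_1 and 0.567 for alpha8, both without amino acids replicate 1, and alpha8 also lost its call without any acetate, lipid, protein or starch array. The count was 222 without amino acids replicate 2, 34 without replicate 1, 21 and 20 without the acetate arrays, 24 and 23 without the protein arrays, 29 without lipids replicate 1 and 30 without starch replicate 2.

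**Figure D2:**
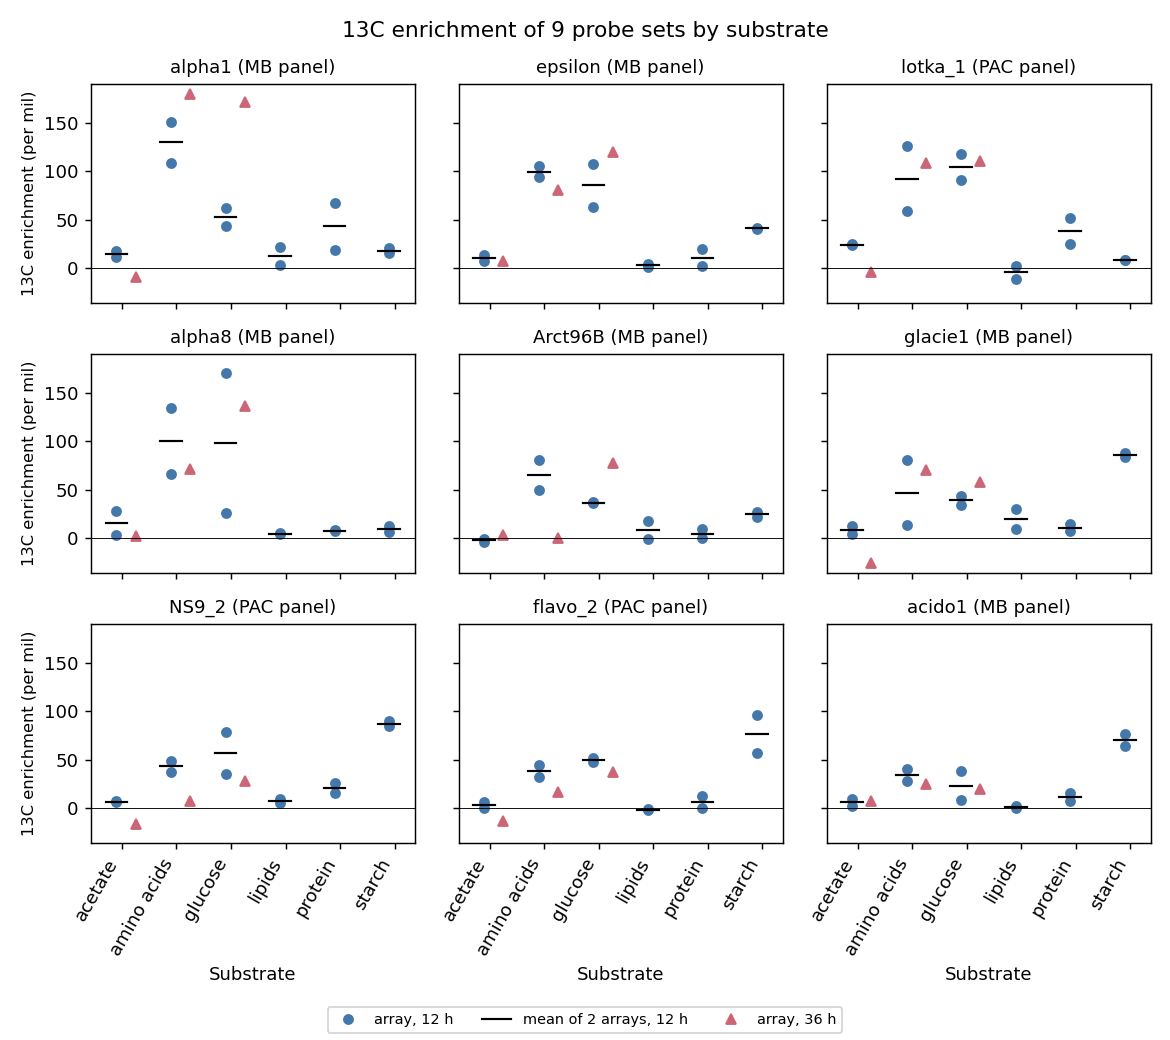
13C enrichment in per mil (y axis) of 9 probe sets by substrate, with each array at 12 h as a circle, the mean of 2 arrays as a line and the single array at 36 h as a triangle. Alpha1 was highest with amino acids at 12 h (mean 130 per mil) and NS9_2, glacie1, flavo_2 and acido1 with starch (means 70.1 to 87.4 per mil).

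**Figure D3:**
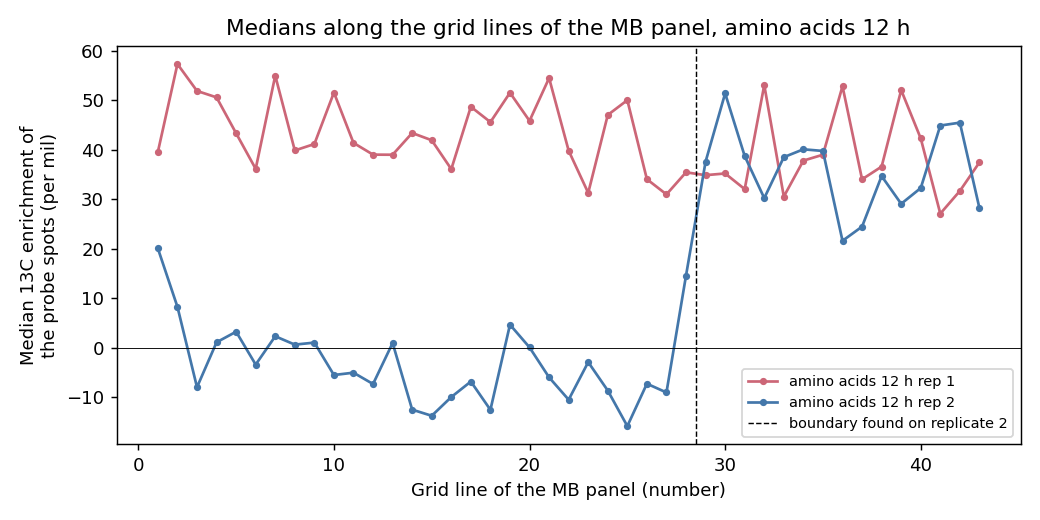
Median 13C enrichment in per mil of the probe spots on each of the 43 grid lines of the MB panel on both amino acid arrays at 12 h. On replicate 2 the median was -3.87 per mil up to line 28 and 35.3 per mil from line 29, the boundary drawn as a dashed line.

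Among the taxonomic groups, members of the other Alphaproteobacteria (those in no named alphaproteobacterial group) were higher with amino acids. Of 24 members, 16 rose and 20 did when adjusted over the list alone, with a median difference of 32.1 per mil against 17.3 over all probe sets (camera, adjusted p = 2.03e-06, and adjusted p = 0.672 with an estimated correlation). With each part of the stepped panel on its own control spots, 1 member rose, and the median was 23.4 per mil against 19.9 over all (adjusted p = 0.0146). Within sets it was 33.3 in A1 to A6 against 3.78 over all and 29.5 in A7 to A12 against 27.2. Relative to the array median, the group lay at 29.8 per mil on the stepped replicate 2, at -0.348 on replicate 1 and at -2.78 at 36 h, so that its excess rested on the stepped array. Bacteroidetes, known for species that degrade polymers, had a median of 10.4 per mil over 43 members (adjusted p = 0.00012, lower than other probe sets, and adjusted p = 0.939 with an estimated correlation), with 1 member called, and 0 adjusted over the list alone. This result depends on leaving out the ambiguous stem bacter. Its 9 probe sets had a median of 34.8 per mil, and all 9 were called, each with a spot in the raised part of the stepped panel. Rhodobacterales had 9.28 per mil over 14 members (adjusted p = 0.00728, lower, and 0.939 with an estimated correlation), with 0 members called by limma and 0 adjusted over the list alone. With the imaging set as a block, the median was 29.6 per mil for the other Alphaproteobacteria (adjusted p = 4.87e-06), 5.47 for Bacteroidetes (0.00023) and -2.61 for Rhodobacterales (0.00107), against 12.2 over all. Within A1 to A6, the set of the stepped replicate 2, the medians of Bacteroidetes and Rhodobacterales were -3.86 and -2.59 per mil, and within A7 to A12 20.0 and 3.16. SAR11, the small-celled clade abundant in surface oceans, had a median difference of 17.4 per mil over 6 members, SAR86 of 21.9 over 9 and Verrucomicrobia of 17.5 over 16, with 0 members called in each and an adjusted p of 0.743.

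With glucose, lotka_1 rose to 104 ± 19.1 per mil (n = 2), which was 72.5 ± 14.003 per mil above the mean of the other 5 substrates (limma, adjusted p = 0.0317). Epsilon was 52.6 ± 11.1 per mil above (adjusted p = 0.0362). Lotka_1 was higher by 42.9 per mil within A7 to A12 and by 82.3 within the starch set, and epsilon by 56.9 and 22.4. These 2 probe sets were the only ones past the threshold, and 23 had an unadjusted p under 0.05. With the imaging set as a block 11 were higher, with lotka_1 at 60.8 per mil (adjusted p = 0.000381) and epsilon at 71.2 (1.47e-05). The count was 0 without glucose replicate 1, either acetate array, either lipid array, protein replicate 2 or either starch array, 1 without protein replicate 1, 14 without glucose replicate 2 and 23 without amino acids replicate 1. It was also 0 under quantile normalization or with the median over spots. Rhodobacterales lay 20.4 per mil above the other substrates in median over 14 members, against 6.91 over all probe sets (camera, adjusted p = 0.00528, and adjusted p = 0.981 with an estimated correlation). All 14 had a difference above 0, 0 passed limma and 3 passed when adjusted over the list alone. Relative to the array median, the group lay at 19.4 per mil on glucose replicate 1 and at -3.25 on replicate 2, so that its excess rested on replicate 1. The median was 20.2 per mil within A7 to A12 (-0.741 over all) and 3.91 within the starch set (-1.75 over all), and 15.4 with the block (3.13 over all, adjusted p = 0.00209).

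Starch, a polymer of glucose, raised 4 probe sets. Glacie1 was 61.6 ± 13.4 per mil above the mean of the other 5 substrates (limma, adjusted p = 0.0247), with 86.2 ± 2.88 per mil against 24.6 (n = 2). NS9_2, of a flavobacterial clade known from marine surveys, was 60.7 ± 10.8 per mil above, flavo_2 57.7 ± 10.6 and acido1 55.1 ± 9.98 (adjusted p = 0.00643 each). Against glucose replicate 2 of the same imaging set, glacie1 was higher by 42.4 per mil, acido1 by 32.2, flavo_2 by 24.9 and NS9_2 by 8.41. With the imaging set as a block, the differences were 34.5, 29.99, 47.8 and 24.5 per mil and none passed (adjusted p = 0.984 to 0.988). The count was 0 without starch replicate 1, 1 without starch replicate 2, 9 without amino acids replicate 1 (8 higher, 1 lower) and 8 without amino acids replicate 2 (6 higher, 2 lower). No taxonomic group differed (camera, lowest adjusted p = 0.0673), and limma called 1 of 7 Alteromonadales and 2 of 43 Bacteroidetes, and as many when adjusted over the list alone.

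Acetate, lipids and protein raised or lowered no probe set against the mean of the other 5 substrates. With acetate, limma called 0 probe sets, and 14 were lower at an unadjusted p under 0.05. The largest differences, which did not pass, were -37.3 ± 11.1 per mil for epsilon (adjusted p = 0.400; -25.9 within A1 to A6 and -93.3 within A7 to A12) and -37.1 ± 13.2 for alpha1 (0.547; -43.7 and -89.6). With lipids limma called 0, and 42 were lower at an unadjusted p under 0.05. Rhodobacter differed by -60.4 ± 24.3 per mil (adjusted p = 0.320; -33.4 within A1 to A6) and lotka_1 by -58.3 ± 14.003 (0.117; -45.4), and neither passed. With protein limma called 0, and 7 were lower at an unadjusted p under 0.05. Alpha8 differed by -38.4 ± 24.6 per mil and epsilon by -37.5 ± 11.1 (adjusted p = 0.992 each; -17.3 and -30.2 within A1 to A6), and neither passed. With the imaging set as a block, 11 probe sets were lower with acetate, 7 with lipids and 3 with protein, the named ones among them. Without amino acids replicate 2, the counts were 3, 69 and 2, and for lipids 3 without amino acids replicate 1 and 1 without glucose replicate 2. Rhodobacterales were higher with acetate relative to other probe sets (camera, adjusted p = 0.0313, and 0.975 with an estimated correlation), with a median of 1.32 per mil against -6.88 over all and a mean of -3.03, opposite in sign. With the block their median was -8.12 per mil against -12.0 over all and the direction of camera down (adjusted p = 0.781). Within sets it was 6.16 in A1 to A6 against -1.42 over all and -23.6 in A7 to A12 against -28.2.

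Protein was set against its monomers, the amino acids, at the same carbon dose. Epsilon had 10.3 ± 12.3 per mil with protein and 99.7 ± 8.17 with amino acids (n = 2 each), a difference of -89.4 ± 14.3 per mil (limma, adjusted p = 0.00439). Alpha1 differed by -87.4 ± 17.1 per mil (adjusted p = 0.0176), Arct96B by -60.7 ± 13.1 (0.0224), eurygrpII5 by -55.6 ± 11.6 (0.0219) and bacter8 by -54.4 ± 13.0 (0.0439). With grid lines centred, epsilon kept its call (-45.9 per mil, limma, adjusted p = 0.0380). Alpha1 (-52.5 per mil, 0.352), Arct96B (-26.2), eurygrpII5 (-14.3) and bacter8 (-16.1, 0.410 for each of these last) lost theirs. With arrays centred, epsilon and alpha1 passed (0.0275 each), and Arct96B (0.0619), eurygrpII5 (0.205) and bacter8 (0.0716) did not. Within A1 to A6, whose only amino acid array is the stepped replicate 2, the differences were -95.2 per mil for epsilon, -65.9 for alpha1, -45.0 for Arct96B, -53.8 for eurygrpII5 and -44.8 for bacter8. In all, 0 probe sets were higher and 7 lower with protein, and with the imaging set as a block 16 were lower, among them all 7. All 7 were probe sets of the raised second part of the MB panel of amino acids replicate 2. With each part of it on its own control spots only epsilon passed (-80.0 per mil, adjusted p = 0.00609), and alpha1 (-78.0 per mil, 0.0611) did not. The median difference of the 7 went from -55.6 to -46.7 per mil (median SE 12.97 and 13.99), against -20.9 and -21.7 over all probe sets. All 7 kept an unadjusted p under 0.05, though they were chosen on the same arrays. Standardised or quantile normalized values, or only the arrays compared, gave 0. The count was 195 without amino acids replicate 2, 20 without replicate 1, 1 without either protein array, 2 without either acetate array, 4 without either lipid or starch array and 16 without either glucose array. The other Alphaproteobacteria were lower with protein (median -31.8 per mil against -20.9 over all; camera, adjusted p = 0.000417, 0.972 with an estimated correlation, 0.334 with the stepped panel on its own controls and 8.98e-06 with the block; -33.0 within A1 to A6 against -0.0617 over all). Of their 24 members 1 fell, 13 did when adjusted over the list alone and 0 did with the stepped panel on its own controls, where the median was -23.1 per mil against -21.7 over all. Bacteroidetes without the stem bacter (median -14.6 per mil, camera, adjusted p = 0.00235) and Rhodobacterales (-11.5 per mil, adjusted p = 0.00553) lay above other probe sets. Each had an adjusted p = 0.972 with an estimated correlation, and 0 members called by limma over all probe sets or adjusted over the list alone. Within A1 to A6 their medians were 7.45 and 8.89 per mil against -0.0617 over all. The amino acid array of that set is the stepped replicate 2, so these values are not independent of the step. With the block their adjusted p was 0.00131 and 0.0233, and with the stepped panel on its own controls 0.0332 and 0.00307 (camera, preset correlation).

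Starch against glucose asked the same of a polysaccharide. Lotka_1 had 8.41 ± 0.120 per mil with starch and 104 ± 19.1 with glucose (n = 2 each), a difference of -95.8 ± 18.1 per mil (limma, adjusted p = 0.0253). It was the only probe set past the threshold, with 3 higher and 14 lower at an unadjusted p under 0.05. Within the starch set it differed by -82.3 per mil, and by the same value with the block (adjusted p = 6.06e-05), where 2 probe sets were lower. Rhodobacterales were lower with starch (median -27.0 per mil over 14 members against -7.20 over all; camera, adjusted p = 0.000111, and 0.990 with an estimated correlation). All 14 had a difference below 0, 0 passed limma over all probe sets and 2 did when adjusted over the list alone, and the glucose side rested on replicate 1 as above. Their median was -3.91 per mil against 1.75 over all within the starch set and with the block (adjusted p = 0.0284). The count of probe sets was 0 without glucose replicate 1, either lipid array or either starch array, 14 without glucose replicate 2 (2 higher, 12 lower) and 6 without either amino acid array (2 higher, 4 lower).

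No probe set passed between lipids and acetate on the per mil scale. By limma 0 passed, and 0 had an unadjusted p under 0.05. The largest differences were -30.8 ± 18.2 per mil for SAR86_2, of an uncultured gammaproteobacterial clade of surface waters, and -28.8 ± 18.1 for lotka_1, and neither passed (adjusted p = 0.996 each; -25.5 and -29.1 within A1 to A6; -10.9 and -12.2 with the block). Under quantile normalization lotka_1 did pass (limma, adjusted p = 0.00384). Rhodobacterales were lower with lipids (median -17.6 per mil against -5.49 over all; camera, adjusted p = 0.0153, and 0.982 with an estimated correlation), with all 14 members below 0 and 0 called over all probe sets or adjusted over the list alone. Within A1 to A6 the median was -13.1 per mil against -4.48 over all, and with the block it was 1.56 against 2.55 over all (adjusted p = 0.277). The block fit called 3 other groups instead: Deltaproteobacteria lower (median -8.20 per mil, adjusted p = 0.0259), and SAR92 and OM60 (12.5, 0.0259) and the other Gammaproteobacteria (13.5, 0.0461) higher, none of which passed with an estimated correlation.

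The 36 h arrays were set against 12 h of the same substrate. With glucose, alpha1 rose from 52.5 ± 13.0 per mil (n = 2) to 172 per mil (n = 1), by 120 ± 20.9 per mil (limma, adjusted p = 0.0114). It was the only probe set past the threshold, with 6 higher at an unadjusted p under 0.05, and it lies in the second part of the MB panel described above. Against glucose replicate 1 of the same imaging set it was 110 per mil higher, as it was with the block (adjusted p = 5.25e-07), where 1 other probe set was lower. The count was 4 without glucose replicate 1 and 0 without glucose replicate 2, where the adjusted p of alpha1 was 0.0955. Under quantile normalization or with grid lines centred, it was also 0. No taxonomic group passed (camera, lowest adjusted p = 0.732), but with the block Rhodobacterales were lower at 36 h (median -13.8 per mil against 0.272 over all, as within A7 to A12; adjusted p = 0.000603), though not with an estimated correlation, under which the block fit called 0 in 180 tests. With amino acids limma called 0 probe sets, with 2 higher and 12 lower at an unadjusted p under 0.05. Planctomycetes was 76.4 ± 21.998 per mil higher at 36 h (adjusted p = 0.240; 41.6 within A7 to A12) and Arct96B differed by -64.8 ± 16.0 (0.115; -80.5 within A7 to A12), and neither passed. With the block 1 was higher and 3 lower, with planctomycetes at 60.5 per mil (adjusted p = 0.0367) and Arct96B at -73.4 (0.00498) among them. Limma called 14 without amino acids replicate 1 (10 higher, 4 lower) and 3 without replicate 2, all lower.

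Some taxonomic groups passed between 12 and 36 h with amino acids, but only with the preset correlation of camera and with 1 array at 36 h. Planctomycetes had a median difference of 11.6 per mil over 11 members (camera, adjusted p = 0.0143) and Rhodobacterales of 13.0 over 14 (0.0333), against -1.08 over all probe sets, while the other Alphaproteobacteria had -16.3 over 24 (0.00197). Each had an adjusted p = 0.957 with an estimated correlation, and limma called 0 members in any, with 1 of Planctomycetes when adjusted over the list alone. Within A7 to A12 the medians were -12.7, -10.2 and -23.1 per mil against -17.7 over all, so that each group stayed on its side of the others. With the block the adjusted p was 0.0121, 0.289 and 0.102, and with the stepped panel on its own controls 0.0639, 0.0460 and 0.175. With acetate limma called 0 probe sets at 36 h against 12 h, and 2 were lower at an unadjusted p under 0.05. The largest differences were -39.6 ± 18.9 per mil for SAR324_1 of the Deltaproteobacteria and -36.2 ± 16.5 for bacter2, and neither passed (adjusted p = 0.982 each; -39.8 and -39.6 within A7 to A12). No taxonomic group passed with acetate (camera, lowest adjusted p = 0.0632, for Rhodobacterales at a median of -21.2 per mil against -3.29 over all). Rhodobacterales did pass with the block (-30.5 against -13.3 over all, adjusted p = 0.00011) and with arrays centred (adjusted p = 0.0219), in both only with the preset correlation (0 of 180 tests with an estimated one), and within A7 to A12 their median was -23.9 against -4.57.

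Of each taxonomic group with at least 3 members, the member with the highest mean over the 15 arrays was alpha1 of the other Alphaproteobacteria (58.8 per mil), rhodobacter of the Rhodobacterales (55.9), fluvii_1 of the Bacteroidetes (44.8), glacie1 of the Alteromonadales (34.8), oceano_1 of the Oceanospirillales (34.0), OM60_2 of SAR92 and OM60 (30.4) and planctomycetes of the Planctomycetes (29.5). Lower means were found for verru8 of the Verrucomicrobia (22.3 per mil), SAR865 of SAR86 (21.9), gamma11 of the other Gammaproteobacteria (21.4), OM43_2 of the Betaproteobacteria (18.7), SAR116_1 of SAR116 (18.6), SAR324_1 of the Deltaproteobacteria (12.9), haptoplastid1 of plastids and eukaryotes (12.3) and SAR11_2 of SAR11 (9.10). The values of fluvii_1 and 890_2_E_2 rested on a few probes: 2 of 12 probes of fluvii_1 averaged 1469 and 113 per mil on the glucose arrays at 12 h and 1270 at 36 h, and the other 10 had medians of -8.14 to 17.4 per mil on the same arrays. For 890_2_E_2, 3 of 12 probes averaged 360 and 317 per mil on the starch arrays, and the other 9 had medians of 24.7 and 18.5 per mil. Alpha1 also varied strongly between its spots. Their SD was 114 per mil on amino acids 12 h replicate 1 (mean 152), 174 on amino acids 36 h (181) and 165 on glucose 36 h (172). The median SD over probe sets on these arrays was 24.5, 28.2 and 14.4 per mil. Other named probe sets varied as strongly. SPOTSAUG01_5m75 had an SD of 150 (mean 113) on amino acids 36 h and of 187 (143) on glucose 36 h. NS9_2 had 84.7 (90.1) on starch replicate 1, and alpha8 136 (171) on glucose 12 h replicate 1. Planctomycetes varied less on amino acids 36 h (SD 20.0, mean 121). So did glacie1 on starch replicate 1 (36.6, 88.2) and lotka_1 on amino acids 12 h replicate 1 (38.9, 126).

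**Figure D4:**
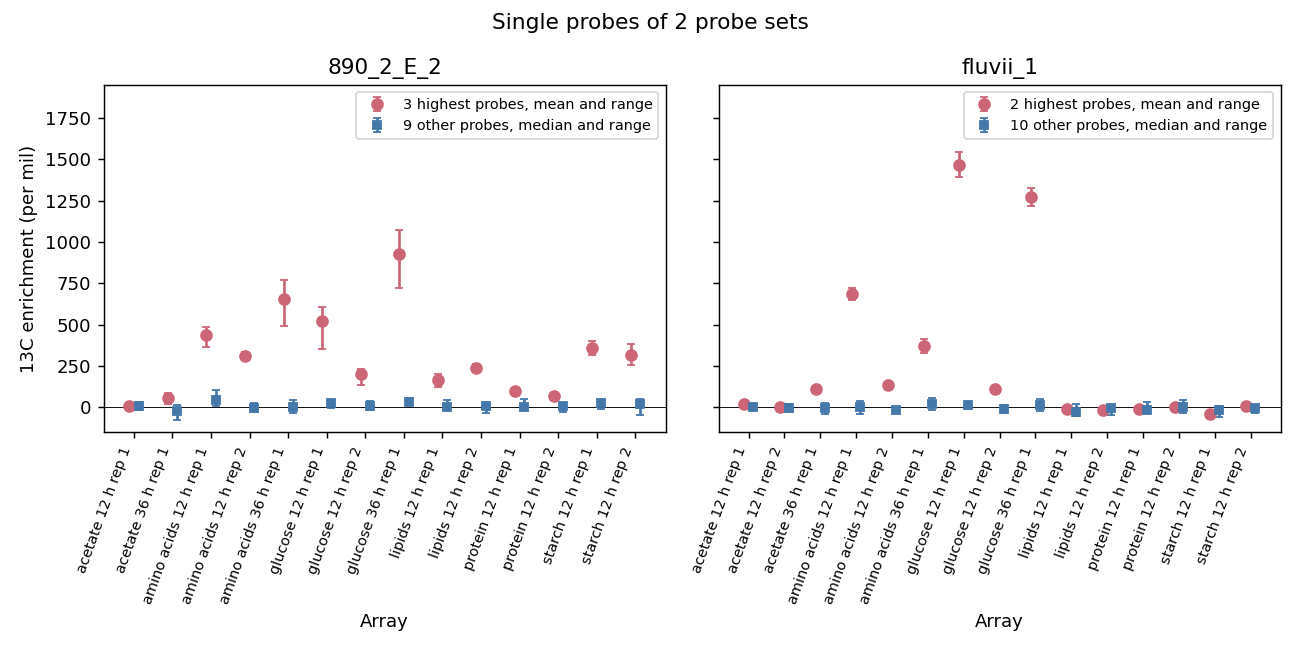
13C enrichment in per mil (y axis) of single probes of 890_2_E_2 and fluvii_1 on each array that measured them, with the mean and range of the highest probes as circles and the median and range of the other probes as squares. The highest probes of fluvii_1 averaged 1469 per mil on glucose replicate 1, and those of 890_2_E_2 930 per mil on glucose 36 h.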

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

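The tests of unnamed spots, control spots, imaging sets, exchanged labels, the panel step and the time differences between substrates were chosen only after the results were seen, and the test of proportional uptake was written before its result.

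Unnamed spots lay outside every comparison and exceeded the control spots on 5 arrays, all of the imaging set A7 to A12 (permutation test over spots, adjusted p = 3e-05 each, from the smallest p the permutations can give, 1e-05). They averaged 114 per mil on amino acids 12 h replicate 1, 107 on glucose 36 h, 79.995 on amino acids 36 h, 56.2 on glucose 12 h replicate 1 and 29.2 on acetate 12 h replicate 1. Between replicates at 12 h, the array median of probe sets moved with them for amino acids and glucose: amino acids replicate 1 lay 35.7 per mil above replicate 2 and glucose replicate 1 17.3 above replicate 2. For acetate it hardly did, since replicate 1 lay 2.86 per mil above replicate 2 while its unnamed spots lay 41.4 ± 3.52 above (SE). Nor did it between glucose 12 h replicate 1 and glucose 36 h, whose medians were 20.0 and 20.4 per mil and whose unnamed spots averaged 56.2 and 107.

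3 explanations for these shifts between replicates were weighed. Counting error of the control spots was argued against, since the 3 panel medians of amino acids replicate 1 lay 5.66 to 7.11 standard errors of the control spots above 0. More label taken up in proportion was predicted to leave probe sets near 0 on replicate 2 near 0 on replicate 1. Those within 10 per mil of 0 on amino acids replicate 2 had a median of 36.8 per mil on replicate 1 (quartiles 29.0 and 49.4, 128 probe sets), and 17.5 for glucose (162 probe sets). That window holds the array median of amino acids replicate 2 (2.81 per mil) and its counting error (median SE 8.71). Small amounts of label there cannot be told from none, so the test cannot decide. A signal shared by spots of no named probe set stays open: unnamed spots of replicate 1 exceeded those of replicate 2 by 134 ± 4.34 per mil (SE) for amino acids and 71.0 ± 3.68 for glucose, but these values prompted the explanation and cannot test it, and the acetate arrays did not follow it. A real difference in labelling between the incubations stays open as untested.

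On the MB panel of amino acids 12 h replicate 2, probe spots of the second part lay 39.1 per mil above those of the first part, and the next largest step of a panel in size was -13.8 per mil. The control spots of the second part lay 27.6 ± 7.80 per mil (SE) above those of the first, as a step in the imaging needs. A control shift of this size was not particular to that panel. On the PAC panel of acetate 12 h replicate 1 it was -28.8 ± 8.18 per mil, where probe spots shifted by -12.5. Uptake of amino acids by the taxa of the raised part was argued against. The same probe sets lay below the others of the MB panel on amino acids replicate 1 (-7.21 ± 3.49 per mil) and at 36 h (-9.09 ± 2.52). The step may therefore add to the differences with amino acids, and 50 of the 54 called probe sets had a spot in the raised part. With each part on its own control spots, 4 of the 54 passed. Their median difference fell from 37.0 to 29.6 per mil, while that over all probe sets went from 17.3 to 19.9. The 54 were chosen by their values on these arrays, so the 51 that kept an unadjusted p under 0.05 do not test the step. How much of the differences the step makes up is not shown.

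Glucose 12 h replicate 2 resembled the starch arrays of its imaging set (Spearman correlation across probe sets 0.639 and 0.725) more than glucose replicate 1 (0.479) or glucose 36 h (0.520), and the starch arrays gave 0.546 with each other. A starch array under the glucose label stays open: in the 20 probe sets with the largest excess of the other glucose arrays over the substrates other than starch (62.1 per mil), it exceeded the starch mean by 21.1 ± 5.24 per mil (SE over probe sets), and in 18 of the 20, but replicates of one substrate differed there by up to 22.1 per mil (amino acids; 5.55 for starch). Single items go against it: lotka_1 had 90.7 per mil on this array against 8.41 ± 0.120 on the starch arrays, and the 2 high probes of fluvii_1 averaged 113 against -41.7 and 6.05, though both were picked after their values were seen. Whether a shared imaging set is the cause cannot be told apart from the substrates: without this array, pairs of one set and different groups correlated by 0.0162 more than pairs of different sets (permutation p = 0.320, spread 0.0383).

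The change of 3 taxonomic groups between 12 and 36 h differed between amino acids and both acetate and glucose with the preset correlation of camera, and none passed with an estimated correlation. Between acetate and glucose no group passed with either (camera, lowest adjusted p = 0.682). Both comparisons that passed share the amino acid arrays, of which one has the stepped panel. Between acetate and amino acids the difference (acetate minus amino acids) had a median of -22.0 per mil for Planctomycetes (camera, adjusted p = 0.0172), -28.8 for Rhodobacterales (adjusted p = 0.00264, below 0 in all 14) and 17.8 for the other Alphaproteobacteria (adjusted p = 0.0172), against -0.496 over all probe sets (each adjusted p = 0.986 with an estimated correlation). Between amino acids and glucose (amino acids minus glucose) it was 1.26 per mil for Planctomycetes (camera, adjusted p = 0.0295), 5.17 for Rhodobacterales (adjusted p = 0.0295) and -27.6 for the other Alphaproteobacteria (adjusted p = 0.000984), against -10.2 over all (each adjusted p = 0.975 with an estimated correlation). Under the block for imaging sets, the adjusted p was 0.0200, 0.000449 and 0.0304 for acetate and amino acids, and 0.248, 0.000102 and 0.0244 for amino acids and glucose, and with arrays centred that of Rhodobacterales for amino acids and glucose was 0.135. With the stepped panel on its own control spots, the adjusted p was 0.0909, 0.00129 and 0.379 for acetate and amino acids, and 0.154, 0.0438 and 0.154 for amino acids and glucose. For single probe sets, limma called 0 in either time difference, with 14 and 12 at an unadjusted p under 0.05. For acetate and amino acids it called 9 (6 higher, 3 lower) with the block and arrays centred and 2, both lower, without amino acids replicate 1. For amino acids and glucose it called 1, lower, with the block, with and without centring, with arrays or panels centred and without either amino acid array at 12 h.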

How the results depend on the processing

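The imaging set, centring, grid line and panel step alternatives, names by grid position and the permutation within imaging sets were chosen after seeing the data, and the others were planned. No paired analysis was possible because the labels give no replicate numbers, and the numbers used here only name arrays in order of deposit. The fluorescence slope was not run, since the fluorescence arrays were not analysed here. Of 792 alternatives to the differences of 30 named probe sets, 616 kept the side of the threshold, 138 lost it and 38 gained it. Where the main or the alternative result passed the threshold, 0 changed direction. A change of direction where neither passed was counted as kept. Of 440 alternatives to the counts and test results, 287 stayed within 1.5 times or on their side. The cause was not tested where none is given. At a minimum of 10 spots, on the log2 ratio scale and with names by grid position, no count moved by over 1.5 times. Signal limits precision through ion counting, with standard errors of 7.44 to 13.7 per mil.

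Counts of probe sets past the threshold follow, with higher and lower ones split where both occur. Without a split, calls with amino acids, glucose and starch against the other substrates were higher, and those with acetate, lipids and protein, of one substrate against another and at 36 h with amino acids were lower. Those at 36 h with glucose were higher. Standardised within arrays, amino acids gave 0 in place of 54, glucose 1 in place of 2, protein against amino acids 0 in place of 7, starch against glucose 2 in place of 1, amino acids at 36 h 2 (1 higher, 1 lower) in place of 0, and the F-test 2 in place of 11. Quantile normalized, amino acids, glucose, protein against amino acids and glucose at 36 h gave 0, lipids, lipids against acetate and the F-test 1, and acetate at 36 h 8 (5 higher, 3 lower). With the median over spots, glucose gave 0, protein against amino acids 14, amino acids at 36 h 1 and acetate at 36 h 1 over control spots in place of 5. With only the arrays compared, protein against amino acids gave 0, starch against glucose 7 and acetate at 36 h 31 (7 higher, 24 lower), from fewer arrays. Array weights gave acetate 22, amino acids 1, glucose 10, lipids 54, protein 5, starch 9 (6 higher, 3 lower) in place of 4, protein against amino acids 1, starch against glucose 10 (2 higher, 8 lower) and the F-test 43.

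The imaging set as a block gave acetate 11, glucose 11, lipids 7, protein 3, starch 2, protein against amino acids 16, starch against glucose 2, amino acids at 36 h 4 (1 higher, 3 lower), glucose at 36 h 2 (1 higher, 1 lower) in place of 1, and the F-test 28. With arrays centred as well, the block gave acetate 8, amino acids 13 (10 higher, 3 lower), glucose 12, lipids 6, protein 3, protein against amino acids 13, starch against glucose 2, amino acids at 36 h 3 (1 higher, 2 lower) and glucose at 36 h 3 (1 higher, 2 lower), so that most calls of the last turned downward. Centring arrays gave amino acids 4, glucose 1, lipids 1, starch 7 (6 higher, 1 lower), protein against amino acids 2 and amino acids at 36 h 3 (1 higher, 2 lower). Centring panels gave amino acids 2, starch 8 (7 higher, 1 lower), protein against amino acids 2 and amino acids at 36 h 3 (1 higher, 2 lower). The stepped panel on its own control spots gave amino acids 4 and protein against amino acids 1. With its second part left out, so that 218 probe sets were tested, amino acids gave 1, glucose 6, lipids 1, protein against amino acids 0, starch against glucose 4 and glucose at 36 h 0. Grid lines centred gave amino acids 3 (2 higher, 1 lower), protein against amino acids 3 (1 higher, 2 lower), starch against glucose 5 (2 higher, 3 lower), amino acids at 36 h 1, glucose at 36 h 0 and the F-test 6.

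With all probe spots of the array as the background, 2 probe sets passed with acetate, 4 with amino acids, 0 with glucose, 1 with lipids, 2 with protein and 7 with starch at 12 h, and 2, 6 and 2 with acetate, amino acids and glucose at 36 h. The taxonomic groups past the threshold numbered 13 of 180 tests with a preset correlation, 0 with an estimated correlation, 7 of 156 tests with the second part of the stepped panel left out (4 of the 13 among them, and 2 of the 13 with the direction turned) and 0 with grid lines centred (3 of the 13 turned). They numbered 14 under the block for imaging sets, 9 of the 13 among them and 1 of the 13 turned. After the probe set means were subtracted, the permutation p of the agreement of arrays was 0.0045 in place of 0.144, and 0.00911 with labels permuted only within imaging sets.

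Leaving out 1 array at a time, with a lone array assumed to vary like the other groups, gave acetate 0 to 3 (highest without amino acids replicate 2), amino acids 20 to 222 (without acetate replicate 2 and amino acids replicate 2), glucose 0 to 23 (without glucose replicate 1 and amino acids replicate 1), lipids 0 to 69 and protein 0 to 2 (highest without amino acids replicate 2), and starch 0 to 9 (8 higher, 1 lower; without starch replicate 1 and amino acids replicate 1). Protein against amino acids gave 1 to 195 (without either protein array and amino acids replicate 2), starch against glucose 0 to 14 (2 higher, 12 lower; without glucose replicate 1 and replicate 2), lipids against acetate 0 to 0, acetate at 36 h 0 to 0, amino acids at 36 h 0 to 14 (10 higher, 4 lower; without amino acids replicate 1) and glucose at 36 h 0 to 4 (without glucose replicate 2 and replicate 1). The F-test gave 2 to 135 (without a lipid array and amino acids replicate 2), and the taxonomic groups 4 to 18 (without amino acids replicate 2 and acetate replicate 2). The permutation p ranged from 0.0130 to 0.509 for array medians (lowest without amino acids replicate 2) and from 0.0406 to 0.486 for the agreement of arrays (lowest without acetate replicate 2).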

Other observations

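The comparisons in this part were chosen only after the values were seen, apart from the test against all probe spots of an array, which was planned.

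Rhodobacter and lotka_1 stood above the probe spots of their array as a whole on both arrays with acetate and with protein, substrates with no probe set above the control spots on both. Above the array median, lotka_1 lay 22.7 per mil higher with acetate (mean of 2 arrays, highest adjusted p = 0.00164 by random draws from all probe spots, panels pooled) and 35.4 with protein (0.0499), and rhodobacter 19.1 with acetate (0.00547) and 35.5 with protein (0.0419). With lipids only 890_2_E_2 did, by 58.3 per mil (0.0039). With starch the 7 probe sets were glacie1 (81.8 per mil), NS9_2 (83.0), flavo_2 (72.4), acido1 (65.7), mrgrpA7 (61.0), OM60_2 (59.2) and 890_2_E_2 (94.1). With amino acids at 12 h they were alpha1 (109 per mil), 890_2_E_2 (90.3), alpha8 (79.7) and lotka_1 (71.8), and with glucose at 12 h 0 passed on both arrays.

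Of 4 families of probe sets outside the fixed groups, formed from the letters of their names, 3 were higher with amino acids at 12 h, and margrpa was not (median 15.5 per mil, 0 of 7 members called, adjusted p = 0.232). All 9 members of bacter, 5 of 6 of alveo and 6 of 10 of eurygrpII passed limma, with median differences of 34.8, 31.3 and 30.8 per mil against 17.3 over all probe sets (camera, adjusted p = 6.2e-05, 0.00329 and 0.000385; adjusted p = 0.109, 0.164 and 0.0470 with an estimated correlation). The called members all had a spot in the raised second part of the MB panel of amino acids replicate 2. Within A1 to A6, which holds that array, the medians were 40.9, 30.1 and 34.7 per mil against 3.78 over all. Within A7 to A12 they were 28.1, 30.6 and 30.8 against 27.2, so that most of their excess lay in the set of the stepped array. With the stepped panel on its own control spots 0, 0 and 1 members passed limma, the medians were 26.0, 22.6 and 29.4 per mil against 19.9 over all, and the adjusted p was 0.0240 for bacter, 0.333 for alveo and 0.00473 for eurygrpII, and none passed with an estimated correlation (adjusted p = 0.542, 0.795 and 0.211 with an estimated correlation). At 36 h against 12 h with amino acids, bacter had a median difference of -31.0 per mil (camera, adjusted p = 1.19e-06, and adjusted p = 0.0784 with an estimated correlation; -28.5 within A7 to A12 against -17.7 over all) against -1.08 over all, with 0 of 9 members called by limma. Alveo and eurygrpII were also lower at 36 h, with medians of -16.2 and -23.3 per mil, while margrpa had 15.8. Within A7 to A12, without the stepped array, the medians of alveo, eurygrpII and margrpa were -21.6, -15.5 and -13.0 per mil against -17.7 over all. There margrpa changed sign and eurygrpII did not lie below the others. With the stepped panel on its own control spots, bacter (camera, preset correlation, adjusted p = 0.000249) and eurygrpII (0.0466) passed, and alveo (0.368) did not. With protein against amino acids, alveo, bacter and eurygrpII had medians of -32.3, -35.1 and -35.8 per mil against -20.9 over all (camera, adjusted p = 0.00459, 0.000435 and 0.000641). None of these passed with an estimated correlation (adjusted p = 0.179, 0.155 and 0.0549). With the stepped panel on its own control spots, the medians were -23.6, -26.3 and -28.5 per mil against -21.7 over all. Only eurygrpII passed there (camera, preset correlation, adjusted p = 0.00807), and alveo (0.322) and bacter (0.0819) did not. Margrpa, with a median of -5.70 per mil with lipids against -14.0 over all, was higher than other probe sets there (camera, adjusted p = 0.00652, and adjusted p = 0.519 with an estimated correlation).

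Of 4318 probes ranked by their mean over the arrays, the 5 highest belonged to 890_2_E_2 and fluvii_1, and the sixth highest had a mean of 179 per mil. The 2 high probes of fluvii_1 averaged 687 and 138 per mil with amino acids at 12 h, 373 at 36 h and 109 with acetate at 36 h, against -41.7 and 6.05 with starch, -6.49 and -17.6 with lipids and -12.0 and 3.92 with protein. The 3 high probes of 890_2_E_2 averaged 440 and 313 per mil with amino acids at 12 h, 655 at 36 h, 520 and 200 with glucose at 12 h, 930 at 36 h, 165 and 239 with lipids and 98.9 and 68.9 with protein.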
